A study of Mus musculus with 2 samples.

How the data were processed

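The deposited values were raw UMI counts per gene and cell, made per the labels with Cell Ranger 3.0.1 on mm10 from 10x Chromium 3' libraries sequenced on a NextSeq 500, and no normalization was applied to them before deposit. The order of the authors' steps, the read filters and the cell-calling settings are not given in the sources used here. The tables held 31058 features: 31053 mouse genes and 5 reporter sequences added to the reference. Coordinates were taken for 31011 genes from GENCODE vM21 on mm10. Raw reads were not analysed here.

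Cells were kept with at least 500 genes and at most 50% of UMIs from genes encoded in mitochondria, which removed 200 of 1967 vehicle barcodes and 230 of 1724 CA3 barcodes. Scrublet, run in each library, marked only 1 vehicle and 3 CA3 cells as doublets, so doublets may remain among the kept cells. The 3257 kept cells were scaled to 10000 counts per cell, log transformed and clustered together with scanpy 1.11.5, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. The 20 clusters, 11 of them proximal tubule, were named from 22 marker lists fixed before the data were examined, and class names are therefore marker-based. Clusters with genes of several segments or lineages were given the broader names distal nephron, T or NK cell and mononuclear phagocyte after the data were seen. T or NK cell joined clusters 12 and 18, while distal nephron was cluster 8 alone and mononuclear phagocyte cluster 15 alone. Proximal tubule clusters 10 and 11 were led by stress genes, among them Cyr61, Fosb and Jun.

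For each class the UMIs of a gene were summed over the cells of a library and divided by the UMIs of all genes not encoded in mitochondria. The ratio was given with the exact conditional binomial interval for 2 Poisson counts and each share of cells with the exact Clopper-Pearson interval. No p-value was computed, since cells of 1 library are not replicates. A count of 0 was set against a floor of 3 UMIs. A median of a gene list was taken over members with at least 20 UMIs in the class, and its percentile came from 10000 lists of the same size, drawn with replacement from the 101 genes nearest in mean CPM.

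Genes were named by a rule fixed before the data were examined. It took genes with at least 30 UMIs summed over the class, at least 50 CPM and detection in 10% of cells, each in the higher library. The ratio had to be at least 1.5 times in either direction, and genes were ranked by the bound of the interval nearest 1. Genes encoded in mitochondria, ribosomal protein genes and predicted gene models were left out. In the proximal tubule class it took up to 12 in each direction, and in each other class with at least 50 cells per library 4. Of each list up to 4 members per class were named, those with the largest absolute log2 ratio, and YAP/TAZ targets, Havcr1, Lcn2, Cdkn1a, Ccl2, Mki67 and the sex label genes were allowed whatever their values. Yap1 in the proximal tubule class, the features alike across classes and the genes of the classes under 50 cells were chosen after their values were seen. The result of 1 list member is not reported here. The 22 gene lists, also fixed in advance, covered YAP/TAZ targets, Hippo components, tubule injury, cell cycle and endocycle, p53 targets, matrix, cytokines, haem and oxidative stress, transport, metabolism, mitochondria, immediate early genes, interferon, unfolded protein response, cell death and macrophage states. Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs.

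To learn what these steps recover, class sums with known ratios were simulated as Poisson counts. This was done for the proximal tubule, distal nephron, endothelial and T or NK classes. In the proximal tubule class the true ratio lay in the interval for 95.3% of 10122 unchanged genes. For genes changed 1.5, 2, 3 and 4 times it did so for 94%, 98%, 100% and 86%. Of the genes that met the naming rule, 76 of 76 in the proximal tubule class were truly changed, against 134 of 212 in the distal nephron, 139 of 340 in the endothelial and 125 of 362 in the T or NK class, so in the small classes genes also met the rule by chance. In the simulation, all 24 genes that the rule named in the proximal tubule class and all 8 in each other class were truly changed. In each class 50 genes had been changed at each ratio, up to 4 times, so the top ranks could hardly hold others. Intervals for Poisson counts were applied to Poisson counts, so their coverage does not extend to counts that vary more between cells. UMIs concentrated in few cells were not simulated, so the simulation does not cover genes that met the rule through few cells.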

Results

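Cells of whole kidneys from female C57Bl/6 mice, 9 weeks old, were profiled by droplet single-cell RNA-seq after rhabdomyolysis. Rhabdomyolysis is the breakdown of skeletal muscle, and the myoglobin it releases injures the kidney tubule. 1 library came from the vehicle group and 1 from the group given CA3, a small molecule known as an inhibitor of YAP1, the coactivator that switches on TEAD-dependent genes when Hippo signalling is low. By its design text, the series looked for pathways and targets in acute kidney injury and in the chronic kidney disease that can follow it. The time between injury and collection, the dose of CA3 and the number of animals per library are not given in the sources used here. The mice carried Pax8.rtTA, TetO.Cre and R26.FUCCI2aR, with which Cre can be induced in tubule cells and a fluorescent cell cycle reporter activated.

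The vehicle library held 1967 barcodes with 19592239 unique molecular identifiers (UMIs) in total and between 3784 and 112355 per barcode. The CA3 library held 1724 barcodes, 17013222 UMIs and between 3506 and 115815 per barcode. Median depth was close, at 7307 and 7278 UMIs per barcode, and the median mitochondrial share was 19.05% and 20.2%. After filtering, 1766 vehicle cells and 1491 CA3 cells were kept, with 17826141 and 15079154 UMIs. Each group had 1 library, so no difference below has a replicate check, and the treatment cannot be separated from the animals, the dissociation or the library. All intervals are 95% intervals that cover counting error only. Ratios are CA3 over vehicle, in counts per 1000000 UMIs of genes not encoded in mitochondria (CPM).

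The labels of sex were checked first. Xist, the RNA that silences an X chromosome in female cells, had 24365 UMIs in the vehicle library and 24085 in the CA3 library. The Y-linked Kdm5d had 1 UMI in each, and Ddx3y, Eif2s3y and Uty had 0 in both, where a count of 0 allows up to 3 UMIs per library. Both libraries therefore read as female.

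The first comparison asked whether the makeup of the kidney cells differed between the libraries. T or NK-like cells, named from T cell and natural killer cell genes such as Cd3g and Nkg7, made up 2.89% of kept vehicle cells (exact Clopper-Pearson interval 2.16 to 3.78%; 51 cells) and 6.44% of kept CA3 cells (5.25 to 7.81%; 96 cells), a ratio of 2.23 (1.57 to 3.20). B-like cells, which carry Cd79a and Ighm, were also a larger share in the CA3 library, at 1.14% (0.666 to 1.82%; 17 cells) against 0.283% (0.0920 to 0.659%; 5 cells). Proximal tubule-like cells, the main transporting cells of the nephron and the usual site of myoglobin injury, were the bulk of both libraries, at 81.1% in the vehicle library (79.2 to 82.9%; 1433 cells) and 77.6% in the CA3 library (75.4 to 79.7%; 1157 cells). Thick ascending limb-like cells, with Slc12a1 and Umod, were 4.02% (3.15 to 5.04%) and 2.75% (1.98 to 3.71%), and the interval of their share ratio of 0.684 (0.454 to 1.02) included 1. Without the cell filter the order turned, to 6.97% and 7.72%. The number of T or NK-like cells was spread over the same 2 clusters in both libraries: cluster 12, led by Ccl5 and Nkg7, held 40 vehicle and 79 CA3 cells, and cluster 18, led by Lef1, Ccr7 and Tcf7, held 11 and 17.

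Shares of the other classes were within counting error of each other in the main clustering. Distal nephron-like cells, a cluster with distal convoluted tubule, connecting tubule and principal cell genes, were 4.42% (78 cells) and 4.43% (66 cells). Endothelial-like cells, led by Emcn, Kdr and Flt1, were 3.91% (69 cells) and 3.35% (50 cells), but 2.15% and 6.24% where each library was clustered on its own and 7.93% and 6.17% at resolution 0.5. Mononuclear phagocyte-like cells, led by Lyz2, Il1b and C1qb, were 2.15% (38 cells) and 2.88% (43 cells). Intercalated-like cells were 0.849% and 1.21%, and podocyte-like cells 0.340% and 0.201%. Dissociation and the viability of each cell type set such shares as well as the makeup of the tissue. Counted among the cells outside the proximal tubule, the T or NK-like share was 15.3% (11.6 to 19.6%) of 333 vehicle cells and 28.7% (23.9 to 33.9%) of 334 CA3 cells, and the thick ascending limb-like share was 21.3% (17.0 to 26.1%) and 12.3% (8.95 to 16.3%).

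**Figure D1:**
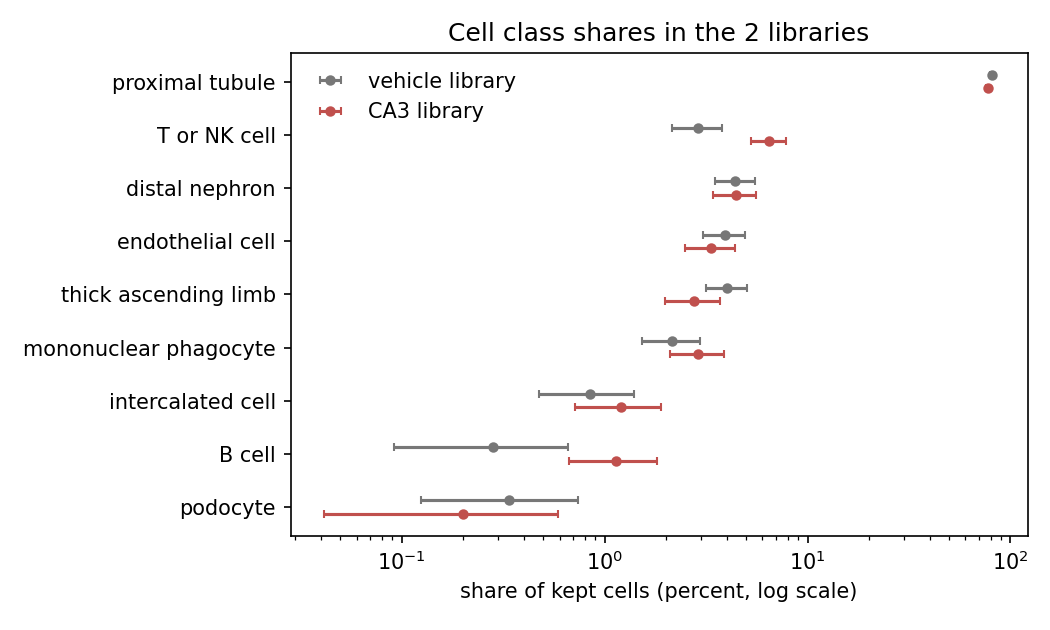
Share of kept cells (percent, log scale) in each marker-named class for the vehicle library (grey) and the CA3 library (red); points are shares and bars are exact 95% Clopper-Pearson intervals, which cover counting error only. The intervals of the 2 libraries are apart for T or NK cells (2.89% and 6.44%) and B cells (0.283% and 1.14%).

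Within the proximal tubule-like class, few of the genes eligible for naming differed by 1.5 times or more. Genes under 50 CPM and predicted gene models were not eligible. Some of these exceeded 1.5 times, such as Ccdc85b (3.23, 2.29 to 4.63) and Gm10076 (2.09, 1.99 to 2.20). Gstp1, a glutathione S-transferase that conjugates electrophiles, ranked first by the naming rule among genes higher in the CA3 library, at 95.7 CPM against 30.5 CPM (ratio 3.14, exact conditional binomial interval 2.76 to 3.58). Itgb6, the beta chain of the integrin that activates latent TGF-beta, was lower, at 113 CPM against 206 CPM (ratio 0.549, 0.509 to 0.591), and so was Plau, the urokinase plasminogen activator, at 38.7 CPM against 71.6 CPM (ratio 0.540, 0.475 to 0.614). The heat shock chaperone gene Hspa1b stood at 47.5 CPM in the CA3 library and 89.5 CPM in the vehicle library (ratio 0.531, 0.473 to 0.596). The share of proximal tubule-like cells with a Gstp1 UMI was 18.6% and 45.9%, and that with Itgb6 was 59.2% and 44.3%, at median depths of 7205 UMIs in the vehicle library and 7917 UMIs in the CA3 library.

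By a rule of size and not of a test, 6 features qualified as higher and 13 genes as lower, of which 12 are named. The count of higher ones was between 10 and 12 without the cell filter, with at least 1000 genes and at most 25% mitochondrial UMIs per cell, without the 50 highest genes in the total and with thinned cells. The other features higher in the CA3 library were Usp50 (1.82, 1.63 to 2.02), Cyp4b1, a cytochrome P450 of the proximal tubule (1.66, 1.52 to 1.82), Pik3c2g, a class II phosphoinositide 3-kinase (1.75, 1.51 to 2.02), Phb, which encodes prohibitin of the inner mitochondrial membrane (1.58, 1.44 to 1.72), and MbmCerulean, a reporter sequence added to the reference (1.75, 1.56 to 1.96). Lower in the CA3 library were also Nme2 (0.564, 0.522 to 0.610) and Nme7 (0.590, 0.537 to 0.646), both of the nucleoside diphosphate kinase family, Aadat, an aminotransferase (0.591, 0.546 to 0.640), Mme, the brush border peptidase neprilysin (0.597, 0.528 to 0.676), Hebp1, a haem-binding protein (0.652, 0.602 to 0.706), and Tmigd1 (0.654, 0.600 to 0.712). Crip1, Hbb-bs and Umod met the rule through very few cells: 3 vehicle cells held 409 of the 586 Crip1 UMIs, 4425 of the 4613 Hbb-bs UMIs and 460 of the 936 Umod UMIs. Without the 3 cells of each library with most UMIs of the gene, the ratio of Crip1 went from 0.381 to 1.19, that of Hbb-bs, a beta-globin gene, from 0.436 to 0.803 (it was 0.0315 without proximal tubule cluster 10), and that of Umod from 0.537 to 0.942. Erythroid markers as a group stood at 837 CPM in vehicle proximal tubule-like cells and 279 CPM in CA3 ones, and 96.8% of the vehicle UMIs lay in 3 cells.

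On mm10, with GENCODE vM21 gene models, Gstp1 lies on chromosome 19 from 4035407 to 4037985, Itgb6 on chromosome 2 from 60598292 to 60722643, Plau on chromosome 14 from 20836660 to 20843385 and Hspa1b on chromosome 17 from 34956436 to 34959238. Usp50 lies on chromosome 2 from 126709096 to 126783470, Cyp4b1 on chromosome 4 from 115624725 to 115647723, Pik3c2g on chromosome 6 from 139587221 to 139969284 and Phb on chromosome 11 from 95666957 to 95680773. Nme2 lies on chromosome 11 from 93949814 to 93956259, Nme7 on chromosome 1 from 164304121 to 164437725, Aadat on chromosome 8 from 60505932 to 60545677, Mme on chromosome 3 from 63241537 to 63386030, Hebp1 on chromosome 6 from 135137522 to 135198022 and Tmigd1 on chromosome 11 from 76902159 to 76916587. The reads of a 3' library fall near the transcript end, and the ends of Gstp1, Nme2 and Usp50 shared 100%, 98.1% and 71.1% of their 31-nucleotide words with transcripts of other genes, so the counts of these 3 genes are uncertain. Cluster 13 of the class, led by Kap, Slc7a12 and Aadat, was 2.30% (1.59 to 3.22%) of vehicle and 0.951% (0.476 to 1.69%) of CA3 proximal tubule-like cells. Without it the ratios of Aadat and Mme were 0.788 and 0.710.

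**Figure D2:**
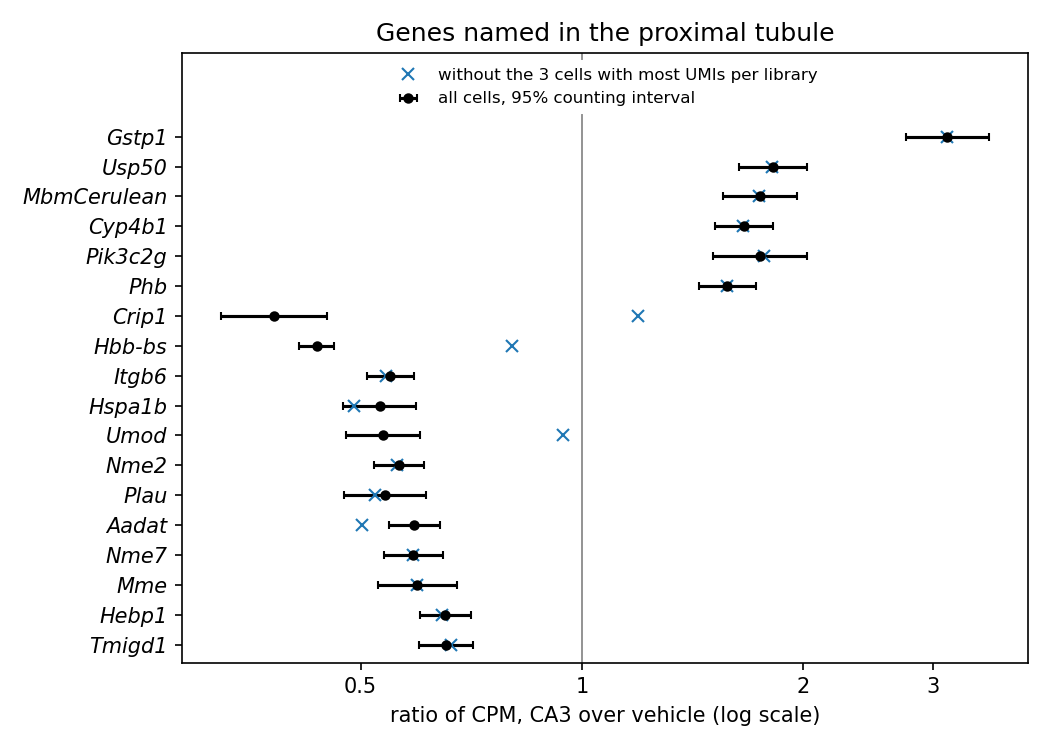
Ratio of CPM, CA3 over vehicle (log scale), for each gene named in the proximal tubule-like class, with the exact 95% counting interval (black) and the ratio without the 3 cells of each library with most UMIs of the gene (blue crosses). Gstp1 stands apart at 3.14, and Crip1, Hbb-bs and Umod move to 1.19, 0.803 and 0.942 without those cells.

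Target genes of YAP and TAZ were the list most closely tied to the compound, and in the proximal tubule-like class they differed little. Of 24 genes, 17 had enough UMIs to be measured, 16 of these lay within 1.5 times of the vehicle level, 1 was lower and 0 were higher. The list's median log2 ratio was -0.073 (interval of the median -0.26 to 0.10), at the 5.76th percentile of 10000 random lists matched on expression, a description of these libraries and not a test. Cyr61, a secreted matricellular protein and a classical YAP target, stood at 0.835 of the vehicle level (0.790 to 0.882; 0.823 without proximal tubule cluster 10), Nuak2, a kinase, at 0.835 (0.761 to 0.915), Amotl2, a feedback regulator of YAP, at 0.808 (0.705 to 0.926), and Crim1 at 0.839 (0.737 to 0.956). Cluster 10, led by Cyr61 and the stress genes Dusp1, Fosb and Jun, was 5.51% (4.39 to 6.82%) of vehicle and 3.54% (2.55 to 4.78%) of CA3 proximal tubule-like cells. Without it the list's median was -0.017. Dock5 was at 1.28 (1.02 to 1.59) but at 0.633 with cells thinned to 2000 UMIs, and Ctgf, a profibrotic target, had 12 and 14 UMIs in the whole class (1.34, 0.577 to 3.18). The member that was lower was Tgfb2, with 23 and 5 UMIs. The 15 measured Hippo pathway components all lay within 1.5 times, with a median of -0.0032 at the 33.3rd percentile, and the largest ratios were 1.16 for Lats1, 0.831 for Tead3 and 0.833 for Amot.

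Injury genes and G2 and M phase genes had few UMIs in these cells. Of 15 measured tubule injury genes, 3 were higher and 2 lower, with a median of -0.019 at the 33.7th percentile. Havcr1, which encodes the injury marker KIM-1, had 10 and 19 UMIs (2.19, 0.969 to 5.27), Krt7 had 18 and 31 (1.98, 1.08 to 3.77), and the low ratios of Vim (0.190) and Anxa2 (0.563) became 0.845 and 1.56 without the 3 cells with most UMIs. Among 10 measured genes of G2 and M phase, 5 were lower and 0 higher, with a median of -0.59 (interval of the median -2.23 to 0.20) at the 1.21st percentile. Mki67, a marker of cycling cells, had 52 and 10 UMIs (0.222, 0.1004 to 0.441) and Cenpf 27 and 5. The Mki67 UMIs came from 8 of 1433 and 5 of 1157 cells, with 45 of the 52 vehicle UMIs in 3 cells. The ratio of Mki67 was 1.17 with at least 1000 genes and at most 25% mitochondrial UMIs per cell. Of 18 S phase genes, 3 were lower, among them Rrm2 (0.369, 0.144 to 0.843) and Rrm1 (0.658, 0.490 to 0.879), and the median was 0.0038 at the 38.6th percentile. Of 17 p53 target genes, 3 were lower and 0 higher, with a median of -0.12 at the 1.71st percentile. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 0.460 (0.348 to 0.602; 193 and 77 UMIs), but at 0.918 without proximal tubule cluster 10, Phlda3 at 0.588 and Plk2 at 0.658. Of 12 endocycle regulators, Cdkn1a was the 1 outside 1.5 times, and the list's median was 0.15 at the 93.0th percentile.

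Metabolic genes stayed close to the vehicle level, with the exception of a few enzymes. All 8 gluconeogenesis genes lay within 1.5 times (median 0.069, 95.4th percentile), and the largest ratios were those of Pck1, the rate-limiting enzyme of the pathway, at 1738 and 2530 CPM (1.46, 1.43 to 1.48), and G6pc at 614 and 804 CPM (1.31, 1.27 to 1.36). Of 16 cholesterol synthesis genes, 1 was higher, Fdps (1.54, 1.31 to 1.81), yet the list's median of 0.18 (0.020 to 0.34) stood at the 99.95th percentile, with Cyp51 on the other side at 0.725 (0.661 to 0.796). Eno1 was at 1.44 (1.37 to 1.51) in a glycolysis list of 13 genes that all lay within 1.5 times (median 0.057, 83.8th percentile). All 19 fatty acid oxidation genes (median 0.0089, 78.6th percentile) and all 20 proximal tubule transport genes (median 0.012, 76.95th percentile) were within 1.5 times, with Acaa1b at 1.19 (1.15 to 1.24), Slc13a3, a dicarboxylate carrier, at 1.19 (1.13 to 1.24) and Slc5a12, a lactate carrier, at 0.827 (0.795 to 0.860). The 22 respiratory chain genes encoded in the nucleus had a median of 0.030 (92.7th percentile). Of the 13 genes encoded in mitochondria (median 0.046, 89.5th percentile), mt-Nd3 was higher, at 1.55 (1.53 to 1.56). It was higher in each of the other larger classes too, from 1.17 (1.10 to 1.24) in endothelial-like to 1.61 (1.56 to 1.65) in distal nephron-like cells.

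Stress and immune lists gave no common direction in proximal tubule-like cells. Of 20 immediate early and dissociation stress genes, 18 lay within 1.5 times (median -0.0057, 55.2nd percentile), with the heat shock genes Hspa1b (0.531) and Hspa1a (0.713, 0.657 to 0.775) low and Hspb1 high (1.61, 1.14 to 2.27). All 19 genes of the haem, iron and oxidative stress list were within 1.5 times (median -8.7e-05, 53.1st percentile), and Tfrc, the transferrin receptor, was at 0.726 (0.636 to 0.829). The unfolded protein and integrated stress list had a median of 0.011 (15 genes, 63.3rd percentile) with Psat1 higher (1.53, 1.20 to 1.96), and the cell death list a median of -0.024 (13 genes, 27.1st percentile) with Bcl2l11, a pro-apoptotic BH3-only gene, lower (0.613, 0.438 to 0.851). The interferon list had a median of -0.17 (14 genes, 1 higher and 4 lower, 6.70th percentile), the matrix and profibrotic list one of -0.10 (13 genes, 3 lower, 10.6th percentile), and Itgb6 was a member of the latter. The cytokine list (median 0.060, 13 genes, 3 higher, 68.1st percentile) and the macrophage list (median 0.17, 14 genes, 4 higher and 2 lower, 98.7th percentile) held transcripts of immune cells at very low counts, such as Ccl5 with 23 and 45 UMIs and C1qa with 3 and 21.

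**Figure D3:**
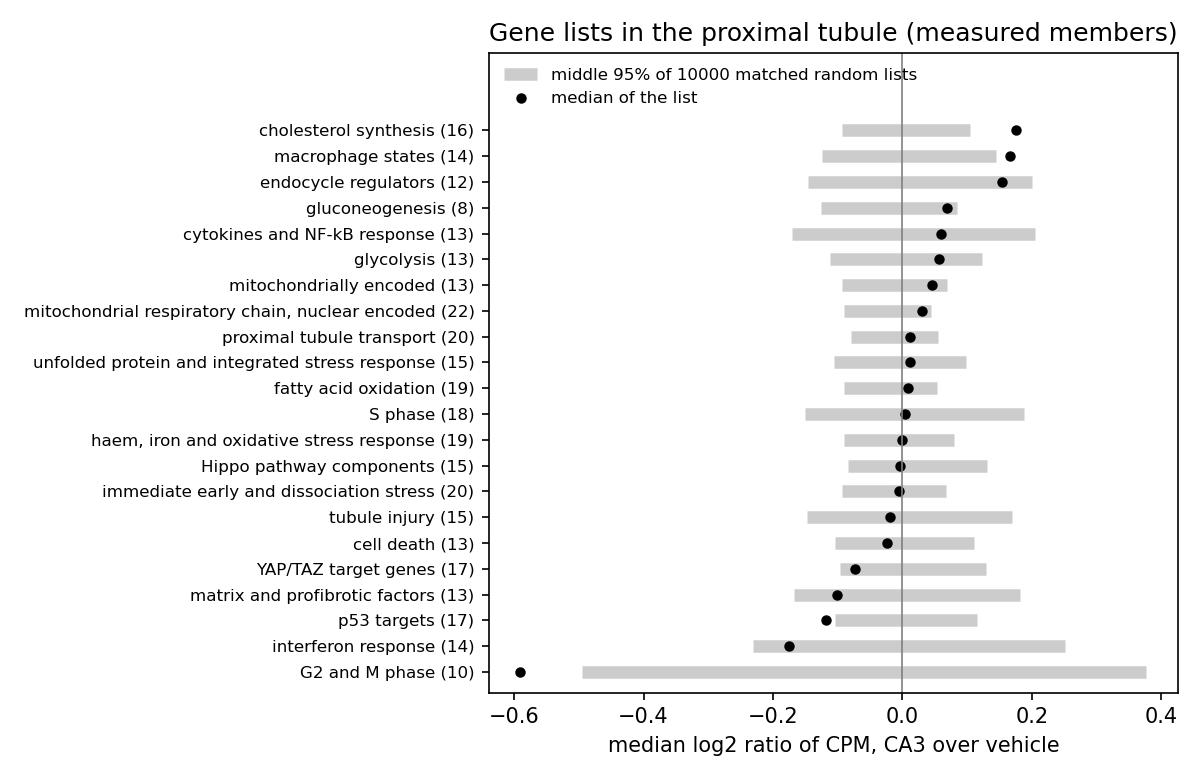
Median log2 ratio of CPM, CA3 over vehicle, of each gene list in the proximal tubule-like class (black points; measured members in brackets) with the middle 95% of 10000 random lists of the same size matched on expression (grey bars). Cholesterol synthesis at 0.18 and macrophage states at 0.17 lie above their bars, p53 targets at -0.12 and G2 and M phase genes at -0.59 below theirs, and YAP/TAZ target genes at -0.073 inside.

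Shares of cells with a UMI were compared at a fixed depth of 2000 UMIs per cell, which left out 0 vehicle and 3 CA3 cells of all kept cells. Cyr61 was found in 14.1% of vehicle and 13.6% of CA3 proximal tubule-like cells (23.2% and 25.3% unthinned), against 0 of 51 and 3.13% of T or NK-like cells, which should lack it. Gstp1 was found in 6.77% (5.52 to 8.20%) and 18.98% (16.8 to 21.4%). Cdkn1a was found in 1.88% (1.25 to 2.73%) and 1.39% (0.795 to 2.24%), so that no difference in the share of positive cells was detectable at this depth, and its share in T or NK-like cells was higher, at 5.88% and 6.25%. Havcr1 was found in 0.349% and 0.520% of proximal tubule-like cells, Lcn2 in 0 of 1433 and 0.173%, Mki67 in 0.279% and 0.260%, Ctgf in 0.0698% and 0.260% and Ccl2 in 0.0698% and 0.173%. Cells with at least 3 G2 and M phase genes were 0.349% and 0.173%, and those with at least 3 S phase genes 0.977% and 1.56% (19.5% and 24.3% unthinned). Unthinned median depth was 7205 and 7917 UMIs in proximal tubule-like cells and 5235 and 6082.5 UMIs in T or NK-like cells.

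Summed over all kept cells, 6 of 23 measured YAP/TAZ target genes were lower in the CA3 library and 1 was higher, and the median of -0.26 (-0.49 to -0.13) lay below all 10000 matched random lists. Ctgf had 553 and 59 UMIs (0.126, 0.0944 to 0.165), Amotl1 336 and 89 (0.312, 0.244 to 0.395) and Igfbp3, the member that was higher, 116 and 244 (2.48, 1.98 to 3.12). 482 of the 553 vehicle Ctgf UMIs lay in 3 cells, without which the ratio was 0.514. The list's median without such cells was -0.30. Yap1 itself was at 0.770 (0.658 to 0.900) in all kept cells and at 0.971 (0.795 to 1.18) in the proximal tubule-like class. Hippo pathway components had a median of -0.18 over 17 genes (0.44th percentile) and matrix and profibrotic factors one of -0.41 over 21 genes, 10 lower and 2 higher, below all random lists. Other lists stood higher. Macrophage states had a median of 0.26 (24 genes, 8 higher and 3 lower), above all random lists. S phase genes stood at 0.24 (22 genes, 1 higher and 2 lower, 99.6th percentile) and tubule injury genes at 0.064 (22 genes, 6 higher and 2 lower, 97.7th percentile). Immediate early and stress genes had a median of -0.22 over 20 genes, with Hspa1b at 0.548 (0.507 to 0.592), Hspa1a at 0.623 (0.589 to 0.659) and Egr1 at 0.682 (0.653 to 0.712). With each cell weighted equally the median of YAP/TAZ target genes was -0.13 and that of Hippo pathway components 0.020. Such sums follow the makeup of the library and its deepest cells as well as levels within a class.

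The distal nephron-like class (78 and 66 cells) differed in genes of several tubule segments. Aqp4 and Plet1 were lower in the CA3 library, at 0.117 (0.0754 to 0.175) and 0.175 (0.108 to 0.270), and 272 of the 331 vehicle UMIs of Aqp4, a water channel of principal cells, lay in 3 cells. Of proximal genes, Slc5a12 and Aqp1 were also lower (0.0445, 0.00529 to 0.167; 0.118, 0.0650 to 0.2003). Of the 189 vehicle Aqp1 UMIs 171 lay in 3 cells, and without the 3 cells with most UMIs per library its ratio was 0.332. Slc5a12 then had 0 CA3 UMIs left, which bounds its ratio at 0.166 or lower. Pck1 (3.83, 3.10 to 4.76), Gstp1 (5.54, 3.03 to 10.8) and Cyp4a10, a fatty acid hydroxylase (3.56, 2.01 to 6.57), were higher. Of the Pck1 UMIs, 63 of 123 vehicle and 198 of 316 CA3 ones lay in 3 cells, and its ratio without these cells was 2.93. In 3 cells also lay 30.9% of the vehicle and 43.6% of the CA3 UMIs of proximal tubule markers in the class. Lcn2, a secreted marker of tubule injury, had a ratio of 2.91 (2.31 to 3.67), but 201 of its 222 CA3 UMIs lay in 3 cells, and the ratio without these was 0.531. The mix of segments differed in the class: principal cell markers stood at 7343 and 5229 CPM, thick ascending limb markers at 7078 and 4557 CPM connecting tubule markers at 38590 and 49370 CPM and proximal tubule markers at 2884 and 3663 CPM. Of 20 proximal tubule transport genes in the class 5 were higher and 6 lower.

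Among the lists in this class, immediate early and stress genes had the lowest percentile (0.08th), at a median of -0.22 (20 genes, 5 lower and 0 higher), with Atf3 at 0.376 (0.253 to 0.545), Dnajb1 at 0.453 (0.311 to 0.647), Ier2 at 0.614 and Egr1 at 0.622 (0.560 to 0.690). Thinned to 2000 UMIs per cell the median was 0.16, and with each cell weighted equally the ratio of Atf3 was 1.01. Tubule injury genes had a median of 0.27 (17 genes, 7 higher and 2 lower, 99.8th percentile), with Spp1, the secreted phosphoprotein osteopontin, at 4111 and 6523 CPM (1.59, 1.53 to 1.65; 0.924 thinned), and a median of -0.15 without the 3 cells with most UMIs of each gene. Gluconeogenesis genes (median 0.32, 8 genes, 99.7th percentile) were led by Pck1, most of whose UMIs lay in 3 cells per library. Whether distal cells made this RNA was not tested. Unfolded protein genes had a median of -0.28 (12 genes, 1.16th percentile). YAP/TAZ target genes had a median of -0.10 (15 genes, 2 higher and 1 lower, 25.2nd percentile) and Hippo components one of -0.042.

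In T or NK-like cells (51 vehicle and 96 CA3 cells), Gzmb, the cytotoxic protease granzyme B, was at 61.0 and 229 CPM (3.75, 2.26 to 6.63), detected in 13.7% and 19.8% of cells, with 77 of its 139 CA3 UMIs in 3 cells (5.69 without the 3 cells with most UMIs per library). Of 11 S phase genes 7 were higher and 0 lower, with a median of 0.65 (99.6th percentile), led by the replication helicase gene Mcm6 with 4 and 31 UMIs (3.56, 1.26 to 13.9). Mki67 went the other way, with 18 and 19 UMIs (0.485, 0.241 to 0.979). T cell markers stood at 4487 and 5102 CPM and natural killer markers at 1895 and 2343 CPM. Tmem248 (4.67, 2.03 to 13.2) and Cd74, the invariant chain of antigen presentation, with 3 and 48 UMIs (7.35, 2.37 to 36.9; 0.0699 where each library was clustered on its own), were also higher, as was Umod, a thick ascending limb gene with 75 of its 95 CA3 UMIs in 3 cells (4.36, 1.31 without them).

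Genes lower in the CA3 library in this class included those of the proximal tubule. Slc4a4, its bicarbonate carrier, was at 0.245 (0.178 to 0.334) and Tmem27, its amino acid transport partner also called collectrin, at 0.352 (0.244 to 0.506), beside Serpinb1a (0.271, 0.160 to 0.451) and the histone gene Hist1h1e (0.358, 0.254 to 0.503). The proximal tubule transport list had a median of -0.76 (12 genes, 8 lower, 0.01st percentile). These transport genes stood at a median of 12.3% of their proximal tubule-like level in vehicle T or NK-like cells and 7.24% in CA3 ones (17 genes), which is a measure of free or captured tubule RNA in the droplets. Such RNA was not even across the class: 54.7% of the vehicle and 54.2% of the CA3 UMIs of proximal tubule markers lay in 3 cells. Erythroid markers stood at 9628 CPM in the vehicle cells, 99.8% of them in 3 cells. YAP/TAZ target genes (5 measured, median -0.045, 47.5th percentile) and interferon genes (9 measured, median -0.011) stood near 0, while Nfkbia, an inhibitor of NF-kB, was at 0.650 (0.524 to 0.808), Egr1 at 2.67 (1.75 to 4.21) and Ly6c2 at 1.99 (1.38 to 2.94). UMIs of Hist1h1e are uncertain, since its transcript end shared 100% of its words with other transcripts.

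Endothelial-like cells (69 and 50) differed most in genes of contractile perivascular cells, held by a few vehicle cells. Myl9 and Des, of smooth muscle and pericytes, had 173 and 117 UMIs in the vehicle library and 0 in the CA3 library, which set against a floor of 3 UMIs bounds the ratios at 0.0363 and 0.0537 or lower. Ptn was at 0.0292 (0.0107 to 0.0641) and Rgs5, a pericyte marker, at 0.0180 (0.00216 to 0.0656). In all 4 cases most of the vehicle UMIs lay in 3 cells (136 of 173, 107 of 117, 399 of 430 and 213 of 233), and pericyte or smooth muscle markers stood at 837 CPM in the vehicle cells, 70.7% of them in 3 cells. Igfbp3, which binds insulin-like growth factors, was higher in the CA3 library, at 102 and 441 CPM (4.30, 3.40 to 5.47; 4.33 without the 3 cells with most UMIs per library), and its ratio was 1.20 where each library was clustered on its own. Ranbp3l (4.44), Slc5a12 (5.46) and Slc13a1 (4.25) were higher too, with ratios of 0.988, 1.67 and 1.97 without such cells.

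YAP/TAZ target genes were best measured in the endothelial-like class, with 22 of 24 members, of which 8 were lower and 3 higher. Their median was -0.072 (29.9th percentile), and -0.63 without the 3 cells with most UMIs of each gene. That trimming took a larger part of the 50 CA3 cells than of the 69 vehicle cells. The shift of all genes under it was not measured, so -0.63 cannot be read as a stronger difference. Ctgf had 525 and 32 UMIs (0.128, 0.0863 to 0.182), with 482 of the 525 in 3 vehicle cells, Axl had 50 and 1, Nt5e 78 and 2, and Amotl1 305 and 57 (0.391, 0.289 to 0.520). In 3 vehicle cells lay 30 of the 50 Axl, 68 of the 78 Nt5e and 169 of the 305 Amotl1 UMIs. Without the 3 cells with most UMIs per library the ratios were 0.195 for Ctgf and 0.646 for Amotl1. Axl and Nt5e then had 0 CA3 UMIs left, which against a floor of 3 UMIs bounds their ratios at 0.314 and 0.628 or lower. Cyr61 was higher, at 1.99 (1.57 to 2.53), but at 0.956 where each library was clustered on its own. Hippo pathway components had a median of -0.47 (16 genes, 5 lower and 0 higher, 0.02nd percentile), with the TEAD-family gene Tead1 at 0.589 (0.420 to 0.813) and Wwtr1, which encodes TAZ, at 0.657 (0.482 to 0.884). Values of this list, Tead1 and Wwtr1 without the 3 cells with most UMIs are not given here. Pericyte or smooth muscle markers stood at 837 CPM in the vehicle cells, 70.7% of them in 3 cells, and were lower in the CA3 cells. Whether Tead1, Wwtr1 or the list were lower in endothelial cells themselves was not tested. The chemokine gene Ccl2 had 111 and 0 UMIs, 103 of the 111 in 3 vehicle cells, and the chaperone cofactor gene Dnajb1 was at 0.511 (0.372 to 0.691). Tubule RNA was part of this class as well: proximal tubule markers stood at 3946 and 5735 CPM. Thick ascending limb markers stood at 3709 and 5953 CPM, with 59.5% and 80.5% of these UMIs in 3 cells. Thin limb markers stood at 2491 and 2490 CPM, with 51.1% and 86.2% in 3 cells. Endothelial markers themselves were at 6647 and 7006 CPM, so ratios of this class cannot be read as those of endothelial cells alone. The medians of the proximal tubule transport (0.75) and gluconeogenesis (0.82) lists became -0.22 and -0.18 without the 3 cells with most UMIs of each gene. The same limit of the trimming holds for both medians.

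A search made after the data were seen looked for features that differed in the same direction in every class where they were measured. It asked for at least 15 UMIs in at least 4 of the 6 larger classes and an absolute log2 ratio above 0.4 in each. Of 7993 features tested, 13 met this, 8 higher and 5 lower in the CA3 library, against a median of 2 and at most 7 in 100 shuffles of the ratios within each class. Higher were Gstp1, Ccdc85b, Gm10076, Hddc3, Btf3l4, Rnf43, Dynlt1f and MbmCerulean, and lower were Nme7, Nme2, Gm10036, Bcl2l11 and Dip2a. The search set no condition on the counting interval, and the intervals of Rnf43 and Dip2a included 1 in every class. In classes under 15 UMIs some features pointed the other way, among them Dynlt1f at 0.299 in endothelial-like and Bcl2l11 at 2.24 in distal nephron-like cells. Gm10076, annotated as a long intergenic RNA, was at 222 and 464 CPM in the proximal tubule-like class (2.09) and higher in all 6 classes. Ccdc85b lies on chromosome 19 from 5453180 to 5457894, Gm10076 on chromosome 14 from 105681828 to 105682211 and Gm10036, a processed pseudogene, on chromosome 18 from 15832794 to 15833327. Transcript ends of Gm10076, Gm10036, Dynlt1f, Gstp1 and Nme2 were at least 79.6% shared with other genes, so these counts are uncertain.

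**Figure D4:**
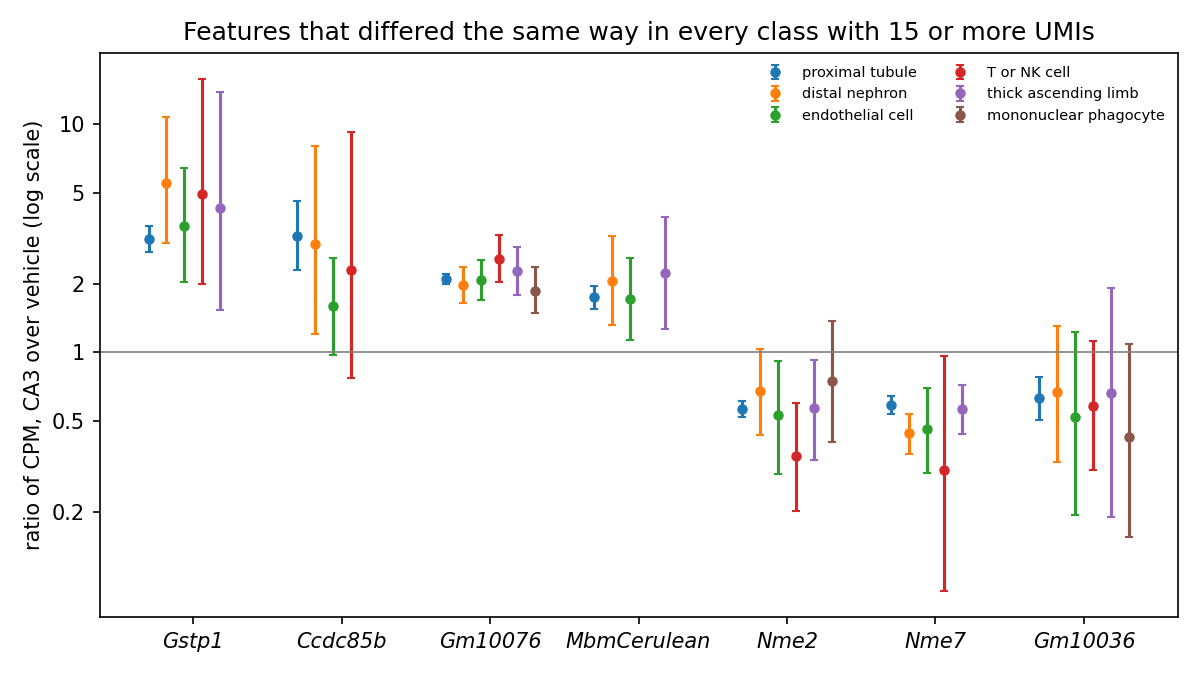
Ratio of CPM, CA3 over vehicle (log scale), of 7 of the 13 features that differed in the same direction in every class with at least 15 UMIs, with exact 95% counting intervals, coloured by cell class. Gm10076 lies near 2 in all 6 classes and Nme2 below 1 in all 6.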

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

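All tests of this part were chosen after the result was seen.

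Reads of 3 reporter sequences stood above the level that a count of 0 allows (0.201% of kept CA3 cells), in data that the comparisons of cell classes and mouse genes did not need, and 2 of them were in a larger share of CA3 cells beyond counting error. At 2000 UMIs per cell, tdimer2 was found in 2.755% of kept CA3 cells and 0.283% of kept vehicle cells, MbmCerulean in 8.938% and 5.38%, and EYFP, whose intervals overlapped, in 1.21% and 0.793%. Unthinned, tdimer2 had 233 UMIs in the CA3 library and 19 in the vehicle library, a ratio of 14.4 (9.04 to 24.4), EYFP had 117 and 72, and EGFP and hrGFPIINLS had 0 in both. FUCCI2aR encodes mCherry and mVenus fusion proteins, whereas these feature names belong to proteins of a Confetti-type reporter, and why they were added to the reference is not given in the sources used here.

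The pattern weighed was that tdimer2 was read in more CA3 cells. Depth is argued against, since at equal depth 2.86% (1.98 to 3.99%) of CA3 proximal tubule cells still had tdimer2, against 0.279% of vehicle ones. A single reporter RNA read under both names in a fixed ratio is argued against too, since tdimer2 per MbmCerulean UMI was 8.755 times higher in the CA3 library (5.18 to 15.9). Free RNA as the source of the reads in tubule cells is argued against as well: T or NK cells and mononuclear phagocytes of the CA3 library held 1 tdimer2 UMI where 22.6 would stand at the proximal tubule level, a ratio of levels of 0.04419 (0.00111 to 0.249). In CA3 proximal tubule cells, 96 of 129 cells with tdimer2 also had MbmCerulean (74.4%, 66.0 to 81.7%), against 18.8% of the others, but they were deeper, with a median of 13927 against 7249.5 UMIs; a difference between the animals in reporter allele or labelling may be the source, stays open and was not tested.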

How the results depend on the processing

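The alternatives without the 3 cells with most UMIs of each gene, without proximal tubule cluster 13 or cluster 10 and with shares outside the proximal tubule were chosen after seeing the data. No paired analysis was possible because each group had 1 library. Of gene list medians 1361 stayed within their interval, 72 moved beyond it and 18 reversed over the alternatives; of gene ratios these were 1738, 170 and 37, of class shares 58, 20 and 0, of shares of cells with a UMI 14 moved and 18 did not, and of counts of genes that met the naming rule 37 moved by over 1.5 times and 79 did not. The alternative UMI minimums cannot change a gene ratio, and each left 132 ratios within the interval. With thinned cells 63 gene ratios stayed within it, 52 moved and 6 reversed. With the mean of per-cell CPM these were 97, 32 and 3, and without the 3 cells with most UMIs 93, 30 and 7. The median of YAP/TAZ target genes in the proximal tubule class stayed between -0.22 and -0.017. The 3 scalings moved the median of all genes by at most 0.0618 log2. The gene ratios and list medians counted here were those of the proximal tubule, distal nephron, endothelial and T or NK classes and of all kept cells. Clustering alternatives have no value for all kept cells as a whole, and list medians have none where no member had enough UMIs. Classes of under 100 cells and genes with few UMIs limit every ratio outside the proximal tubule. Leaving out 3 cells per library takes a larger part of the smaller class sum, and totals were not recomputed, so it can itself shift a ratio. Except where few cells hold a gene's UMIs, the cause was not tested.

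Without the cell filter, the shares in the vehicle and CA3 libraries were 77.3% and 71.8% for proximal tubule, 5.60% and 6.16% for distal nephron and 6.97% and 7.72% for thick ascending limb. In the proximal tubule 10 genes met the naming rule as higher, against 6, and Crip1 was at 1.21, Hbb-bs at 2.40 and Anxa2 at 1.45; over all kept cells mitochondrially encoded genes had a median of 0.11. With at least 1000 genes and at most 25% mitochondrial UMIs, proximal tubule was 75.9% and 70.1%, T or NK 4.09% and 9.19%, mononuclear phagocyte 3.45% and 4.40%, and in the vehicle library distal nephron 3.21% and endothelial 2.65%; 11 proximal tubule genes met the rule as higher. There Crip1 was at 1.30, Hbb-bs at 2.51, Vim at 1.05 and Mki67 at 1.17 in the proximal tubule, Slc13a1 at 0.935 and Clu at 1.90 in endothelial cells, and medians were 0.028 for endothelial cytokines, -0.0042 for endothelial haem and oxidative stress and -0.043 for T or NK mitochondrially encoded genes.

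At resolution 0.5, mononuclear phagocytes were 3.96% of CA3 cells and endothelial cells 7.93% and 6.17%, with Crip1 at 1.23 and Anxa2 at 1.48. At resolution 2, endothelial cells were 2.21% of vehicle cells, with Crip1 at 1.25, Anxa2 at 1.29 and Ifit1 at 0.1005 in the proximal tubule, Clu at 1.91 in endothelial cells and a median of 0.0013 for endothelial cytokines. With each library clustered on its own, endothelial cells were 2.15% and 6.24%, Crip1 was at 1.23 and Anxa2 at 1.48, endothelial Cyr61 at 0.956 and Clu at 7.15, T or NK Cd74 at 0.0699 and Xbp1 at 0.460, and the medians of endothelial cytokines and T or NK mitochondrially encoded genes were 0.023 and -0.11.

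Without the 50 highest genes in the total, 11 proximal tubule genes met the rule as higher, and 12 did with cells thinned to 2000 UMIs. With the mean of per-cell CPM, Spp1 was at 0.955 and Atf3 at 1.01 in distal nephron and Slc5a12 at 0.863 in endothelial cells; endothelial medians were 0.28 for matrix, -0.11 for haem and oxidative stress and -0.029 for transport, and over all kept cells 0.020 for Hippo and 0.0095 for mitochondrially encoded genes. Thinned to 2000 UMIs, Dock5 was at 0.633, Vim at 1.45 and Ifit2 at 1.24 in the proximal tubule, Spp1 at 0.924 and Ier2 at 1.12 in distal nephron and Ranbp3l at 0.46 in endothelial cells, with endothelial medians of -0.11 for haem and oxidative stress, -0.15 for transport and -0.12 for gluconeogenesis. Without the 3 cells with most UMIs, Crip1 was at 1.19, Anxa2 at 1.56 and Ifit1 at 0.838 in the proximal tubule, distal Lcn2 at 0.531, endothelial Ranbp3l at 0.988, Clu at 1.14 and G6pc at 0.797, and the same 3 endothelial medians were -0.088, -0.22 and -0.18.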

Other observations

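The tests of free RNA, of the yield of tubule cells and of the genes with no shared end were chosen after the result was seen; those of the count of genes with shared ends, a chromosome segment and the cell filter were chosen before their results were seen.

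Thick ascending limb-like cells (71 vehicle and 41 CA3 cells), too few for the comparisons above, differed in tubule injury and macrophage genes, in part through few cells. Lcn2 stood at 31.7 and 250 CPM (7.88, 4.89 to 13.2; 5.70 without the 3 cells with most UMIs per library), the actin-binding thymosin gene Tmsb10 at a ratio of 4.93 (2.74 to 9.23) and Spp1 at 5716 and 13503 CPM (2.36, 2.26 to 2.46). Of 11 measured tubule injury genes 7 were higher and 0 lower, with a median log2 ratio of 0.90, and 3 CA3 cells held 67.7% of the UMIs of injured tubule markers. Of 10 macrophage genes 7 were higher and 0 lower (median 1.21), with 121 of the 124 CA3 UMIs of Cd74 and 50 of the 53 of H2-Aa in 3 cells. Immediate early genes were lower, with 11 of 19 lower and 0 higher (median -0.85), among them Fos at 0.329 (0.276 to 0.391) and Junb at 0.435. Proximal tubule markers stood at 4055 CPM in the vehicle cells of the class and 997 CPM in the CA3 cells. List medians of this class and of the mononuclear phagocyte-like class were not run through the processing alternatives. Gene ratios of both classes were run only without the 3 cells with most UMIs.

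Mononuclear phagocyte-like cells (38 and 43) had less Il1b, the interleukin-1 beta gene, in the CA3 library, at 2028 and 954 CPM (0.471, 0.415 to 0.533; 0.429 without the 3 cells with most UMIs per library), and less Tnfaip3 (0.487, 0.344 to 0.685), while Cxcl2, a neutrophil chemokine gene, was higher (2.27, 1.90 to 2.72). Of 15 cytokine genes 5 were lower and 2 higher, with a median of -0.49. Other cell types stood in the class as well: neutrophil markers were at 284 and 5186 CPM (96.2% of the CA3 UMIs in 3 cells) and erythroid markers at 30.5 and 11766 CPM (99.8% in 3 cells), with S100a8, a neutrophil gene, at a ratio of 18.8 (13.4 to 27.0) and Hbb-bs at 370 (170 to 1010). Of 23 macrophage genes 3 were higher and 5 lower (median -0.14), with the complement gene C1qa at 1.73 (1.51 to 1.99).

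The 13 features that differed in the same direction in every class measured form the next pattern. Of the 12 genes with an annotated end, 5 (41.7%) shared at least 50% of the end with other genes. This compares with 3.17% of 15048 genes and at most 4 in 10000 matched draws. The counts of these 5 may therefore be affected by reads shared with near-identical copies. Per the labels both libraries were counted with the same program and genome build. Shared ends as the explanation of these 5 thus need a further difference between the libraries, which was not tested. The 7 genes with no shared end were picked by that same measure, so their test could not have come out otherwise. It shows only that the last 300 nucleotides of their longest transcripts are not shared. Shuffled ratios gave a median of 2 and at most 7 such features, so chance stays open for some of the 13. Free proximal tubule RNA is argued against for most, since the 13 features stood at a median of 93.02% of their proximal tubule level in CA3 T or NK cells. There 11 stood above the highest transport gene at 15.8%, 3 of them (Btf3l4, Hddc3 and Dip2a) on 5 UMIs or fewer. The other 2, Nme7 at 13.01% and MbmCerulean at 10.2%, lay within the range of the transport genes. Free RNA therefore stays open for these 2 in T or NK cells. Transport genes also stood higher in vehicle T or NK cells, at a median of 12.3% against 7.24%. In CA3 distal nephron cells Nme7 and MbmCerulean stood at 210% (172 to 253%) and 77.85% (57.4 to 103%) of their proximal tubule level. Transport genes stood at 19.01% at most, which argues against free RNA for these 2 in that class. A chromosome segment that differs between the animals stays open for Gstp1 and Ccdc85b, both on chromosome 19: the 131 other genes of its first 10 Mb stood at the 32.96th percentile of 6979 runs of neighbouring genes. An effect of CA3 in every cell class is a hypothesis that 1 library per group cannot separate from the animal or the library.

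The larger shares of T or NK and B cells in the CA3 library form the last pattern. A lower yield of proximal tubule cells is argued against, since it would raise every other class alike, and the thick ascending limb share ratio was 0.684 (0.454 to 1.02), with an interval apart from that of T or NK cells (1.57 to 3.20). The mitochondrial filter is argued against as well, since without the cell filter the T or NK share ratio was 2.149 (1.51 to 3.08). Without that filter the thick ascending limb shares were 6.97% and 7.72%, so the order of that class depends on the filter, and the difference between the libraries was smaller than that of T or NK cells. Blood left in the kidney, a difference in dissociation and more lymphocytes in the tissue stay open and may each give such shares; none was tested.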
